A study of Homo sapiens with 12 samples.

How the data were processed

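Gene expression was measured on 12 HG-U133 Plus 2 oligonucleotide arrays, 3 in each of 4 groups: 786-O cells with myoblasts, 786-O cells alone, PC3 cells with myoblasts and PC3 cells alone. The authors deposited 1 linear signal intensity per probe set and array. MAS5 was the only tool that the submitters' notes named, and its version was not stated. The values had a floor near a signal of 4.5 near which 49.8% of them lay (between 2.0 and 2.5 on the log2 scale), and the distributions of the arrays nearly coincided, so a background model and a normalization between arrays that the notes do not name may lie behind them. The deposited intensities ran from 3.314 to 73706.3, and both deposited tables held the same values for 54675 of 54675 probe sets. The authors' table also gave a signed fold-change score and an unadjusted p-value for each pair of groups.

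Signals were used as deposited and taken to log2 without an added constant. A probe set entered if its mean log2 signal over the 12 arrays was above the median probe set's, 2.65. Control probe sets (62), probe sets without a gene symbol (13166) and probe sets with several (1522) were left out, which left 39925 before the filter on dim signals. The gene identifiers of 38545 of them (96.5%) were found in the human gene reference table, from which 7383 symbols were brought up to date. Where several probe sets of a gene entered, the one with the highest mean was used, so that 12502 genes were tested. A signal of 16 (log2 of 4) was taken as the floor after the data were examined; the 27 control probe sets for transcripts that were not added reached 5.02 at most. Where all 3 arrays of a group lay under the floor, the fold is given as a lower bound against it, and likewise, as decided after the values were seen, where only the mean of the group lay under it.

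The 4 groups were fitted together in limma 3.58.1 (R 4.3.3) with an intensity trend in the empirical Bayes step. The contrasts, 5 in number, were co-culture against alone in each line, the difference between those responses, and 786-O against PC3 alone and in co-culture. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes, and genes with an adjusted p under 0.05 were called. Errors of log2 fold changes are standard errors from this fit, with 3 arrays per group, and the number of arrays limits their precision. The fit takes 1 spread per gene over all 4 groups. Where a gene hardly varied near the floor in 1 line, its error and p-value in the other line can be too small. For CCL20, log2 signals ran from 4.74 to 6.73 in PC3 alone but only from 2.14 to 2.48 in 786-O. The co-cultured 786-O arrays also varied more than those of 786-O alone. Errors and p-values of the 786-O response can therefore be too small for brighter genes as well. No statement was found that the repeats were separate cultures, so the p-values measure only the spread between these samples. Positions in the genome are not given, since the tables identify genes by symbol and probe set.

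Gene lists, 38 in number, were fixed before the data were examined, and the 36 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each contrast. The genes named were fixed by rule at the same time. They were the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (this last condition was not set for the difference of responses), and up to 4 members with the smallest p of each list described. Of the 10 largest rises in each comparison between the lines 9 are named, and 1 gene was left out of the text. Genes outside the rule are marked where they appear. Overlaps between the responses were tested with Fisher's exact test. The alternatives tried were quantile normalization, centring on the array median, other filters, an added constant, other variance models, array weights, other ways of choosing probe sets, a block for the repeat number, stricter thresholds and the omission of each array.

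The fit was tested on simulated data with 12502 genes and the same groups. In the 786-O response it called 50% of genes changed by a log2 value of 0.5, 81.8% at 1 and 96.1% at 2, and 5.6% of its calls were false. In the PC3 response the shares were 40.9%, 83.8% and 93.9%, with 7.6% of calls false, the highest of the 5 contrasts. For the difference of responses they were 27%, 81.4% and 92.5%, with 6.2% of calls false. The simulated noise was independent between genes and had 1 spread per gene in all 4 groups. The real co-cultured 786-O arrays varied more. Their deviations from the other arrays of the group had an SD across genes of 0.298 to 0.507, against 0.221 to 0.2285 in 786-O alone. The simulated shares therefore need not hold for these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.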

Results

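The series asked how 2 human cancer cell lines change their gene expression next to muscle progenitor cells. 786-O is a renal carcinoma line that lacks a functional VHL protein, and PC3 is a prostate carcinoma line. Each was grown alone or under primary myoblasts from the limbs of 5-day-old mice, which sat in the upper chamber of a transwell plate, so that the cells shared medium without touching. RNA of the cancer cells was taken 12 h after the myoblasts were added, on 3 arrays per group. The labels give 30000 cancer cells seeded 6 h before 10000 myoblasts, and elsewhere a 1:1 co-culture. They do not say whether the wells without myoblasts had the same 6 h before the count of hours began, and the lines were kept in different media (RPMI1640 and F-12K).

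The arrays were alike in depth. The median signal per array lay between 5.46 and 5.73, and 39.67% to 40.18% of probe sets reached a signal of 32. One array stood apart: replicate 2 of co-cultured 786-O had a ratio of 3' to 5' signal of 7.22 for ACTB, against 3.08 to 4.24 on the other 11 arrays, and of 1.84 for GAPDH, against 1.07 to 1.29. Its correlation across probe sets with the other arrays of its group was 0.978 to 0.983, while replicates 1 and 3 reached 0.995 with each other. The labels give an RNA integrity number of 10 for all samples. ACTB, the cytoskeletal actin used as a reference, differed between co-culture and alone by a log2 value of 0.02 ± 0.02 (SE, n = 3 per group) in 786-O and 0.04 ± 0.02 in PC3, and neither passed the test (adjusted p = 0.579 and 0.375).

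**Figure D1:**
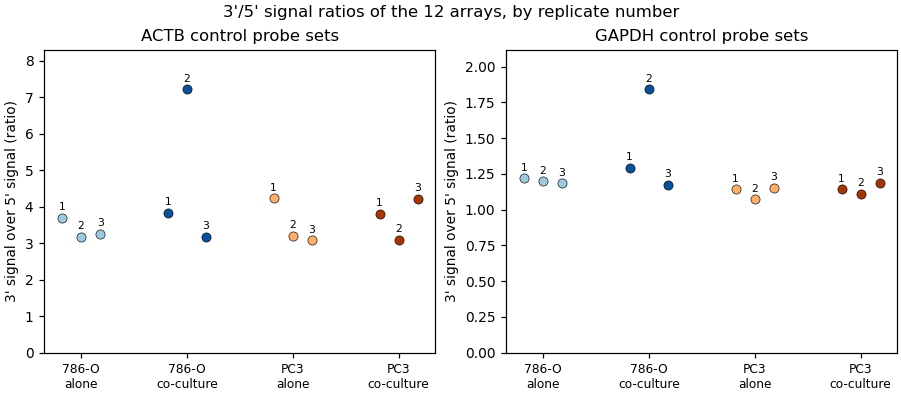
Ratio of the 3' to the 5' control probe set signal of ACTB (left) and GAPDH (right) on each of the 12 arrays, 3 per group, with the replicate number above each point. Replicate 2 of co-cultured 786-O lies at 7.22 and 1.84, above all other arrays.

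The first comparison asked what 786-O cells changed when myoblasts were present. NLRC5, the activator of MHC class I genes, rose with a log2 fold change of 2.54 ± 0.28 (SE, n = 3 per group, adjusted p = 0.000393), and CXCL1, a chemokine that draws neutrophils, rose with 2.18 ± 0.16 (adjusted p = 2.5e-05). NOTCH3, a Notch receptor, lay under the floor in all 3 arrays grown alone and was at least 3.52-fold higher in co-culture (adjusted p = 1.49e-05). EGR3, an immediate early transcription factor induced by growth factors, fell by 3.30 ± 0.16 on the log2 scale (adjusted p = 7.63e-07). COL12A1, a fibril-associated collagen, fell by 1.68 ± 0.18 (adjusted p = 0.000338).

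Among the other large rises, AMBN, an enamel matrix protein, was at least 3.67-fold higher and KRT79, a keratin, at least 5.83-fold higher, and LOC285628 and PDLIM4 had log2 fold changes of 2.19 and 2.18. Among the large falls, RTN1 was at least 1.85-fold lower, MAGEB2 at least 1.39-fold, ZNF28 at least 1.66-fold and UNC5B, a netrin receptor, at least 2.87-fold, while CXADRP1 fell with a log2 fold change of -1.80. The remaining 6 of the 20 largest changes lost their call when some single arrays were left out. Those were CYP1B1, a cytochrome P450 (adjusted p = 0.0623 without replicate 2 grown alone), OLIG2 (0.0762), LOC649305 (0.0812) and ARSL (0.0666), each highest without replicate 3 grown alone, and DACH1 (0.0558) and NUDT10 (0.11), each highest without replicate 2 grown alone.

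Targets of the hypoxia-inducible factors, which raise glucose uptake and blood vessel growth, rose as a group in 786-O. Of 30 measured members 12 rose and 0 fell, or 15 and 2 adjusted over the list alone, with a median log2 change of 0.26 (camera adjusted p = 0.00146; adjusted p = 0.205 with an estimated correlation). NDRG1, a stress-response gene, rose with a log2 fold change of 0.79 ± 0.03 (adjusted p = 1.42e-07), DDIT4, an inhibitor of mTOR signalling, with 0.91 ± 0.06 (adjusted p = 1.49e-05), ADM, a vasodilator peptide, with 0.53 ± 0.09, and SLC2A1, the glucose transporter GLUT1, with 0.51 ± 0.08. Genes of the ATF4 amino acid response rose as well: 13 of 27 rose and 0 fell, or 14 and 0 adjusted over the list alone, with a median of 0.24, or 0.23 with signals under the floor set to it (adjusted p = 6.06e-05; adjusted p = 0.192 with an estimated correlation). They included SLC7A11, a cystine transporter, at 0.51 ± 0.07, PCK2, the mitochondrial PEP carboxykinase, at 0.57 ± 0.10, ALDH1L2, a mitochondrial folate enzyme, at 0.91 ± 0.17, and CEBPB, a transcription factor, at 0.38 ± 0.07. Without replicate 2, the array that stood apart, the median over both lists was 0.196 in place of 0.237.

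Antigen presentation genes rose in 786-O, with 5 of 17 higher and 0 lower (7 and 0 adjusted over the list alone), among them TAP1, a peptide transporter, at 0.73 ± 0.10 and PSMB9, an immunoproteasome subunit, at 0.72 ± 0.15. The list's median was 0.19 (adjusted p = 0.0383; adjusted p = 0.192 with an estimated correlation). YAP and TEAD targets, which answer to cell shape and density, fell with 0 of 16 higher and 3 lower (0 and 6 adjusted over the list alone), including TGFB2, a growth factor of the TGF-beta family, at -0.72 ± 0.10 and CRIM1 at -0.31 ± 0.05. Their median was -0.13 (adjusted p = 0.0163; adjusted p = 0.192 with an estimated correlation). Both of these calls were lost without replicate 1 (adjusted p = 0.0579 for each) and without replicate 3 (0.0852 for each) of the co-culture, and the YAP and TEAD call also without a filter on dim probe sets (0.0863).

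Lists that did not pass in 786-O held single genes that did. NF-kappaB target genes had 7 of 24 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0848), with ICAM1, an adhesion molecule, at 0.52 ± 0.09, CXCL8, the chemokine interleukin-8, at 0.56 ± 0.11 and IL11, a cytokine, at -0.55 ± 0.11. TGF-beta and SMAD targets had 3 of 21 higher and 5 lower (4 and 9 adjusted over the list alone; adjusted p = 0.0602): the inhibitors of differentiation ID1 and ID3 fell, at -1.06 ± 0.14 and -0.93 ± 0.12, and FN1, fibronectin, rose at 0.78 ± 0.13. Feedback genes of FGF and ERK signalling had 3 of 18 higher and 4 lower (3 and 5 adjusted over the list alone; adjusted p = 0.351), with SPRY4, an inhibitor of the pathway, at -1.42 ± 0.16.

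In all, 1498 of 12502 genes were called in 786-O, 1010 higher and 488 lower, of which 169 and 38 changed at least 2-fold. The groups of 35.3% of all genes did not overlap, where chance gives 10%. Neither did those of any called gene named in this comparison or in the 3 others between pairs of groups. That adds no support, since non-overlap was a condition for naming the largest changes and list members were picked by smallest p. The count was 759, 536 and 604 without replicates 1, 2 and 3 grown alone, 2522 without replicate 3 of the co-culture, and 1546 without its replicate 2, with 1133 of the 1498 genes called again in the same direction. It was 175 when only the 6 arrays of 786-O entered the fit, of which 166 were among the 1498, and of the named genes 24 kept their call and 74 lost it. With the ACTB ratio in the fit, added after the data were seen, 1091 genes were higher and 927 lower, with 1252 of the 1498 called again in the same direction. Without a filter 963 genes were called, and with weights fitted gene by gene, also added later, 4087. Array weights did not converge, gave nearly no weight to replicate 1 of the co-culture, and left 309. With each array centred on its median 1375 genes were called, 847 higher and 528 lower.

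**Figure D2:**
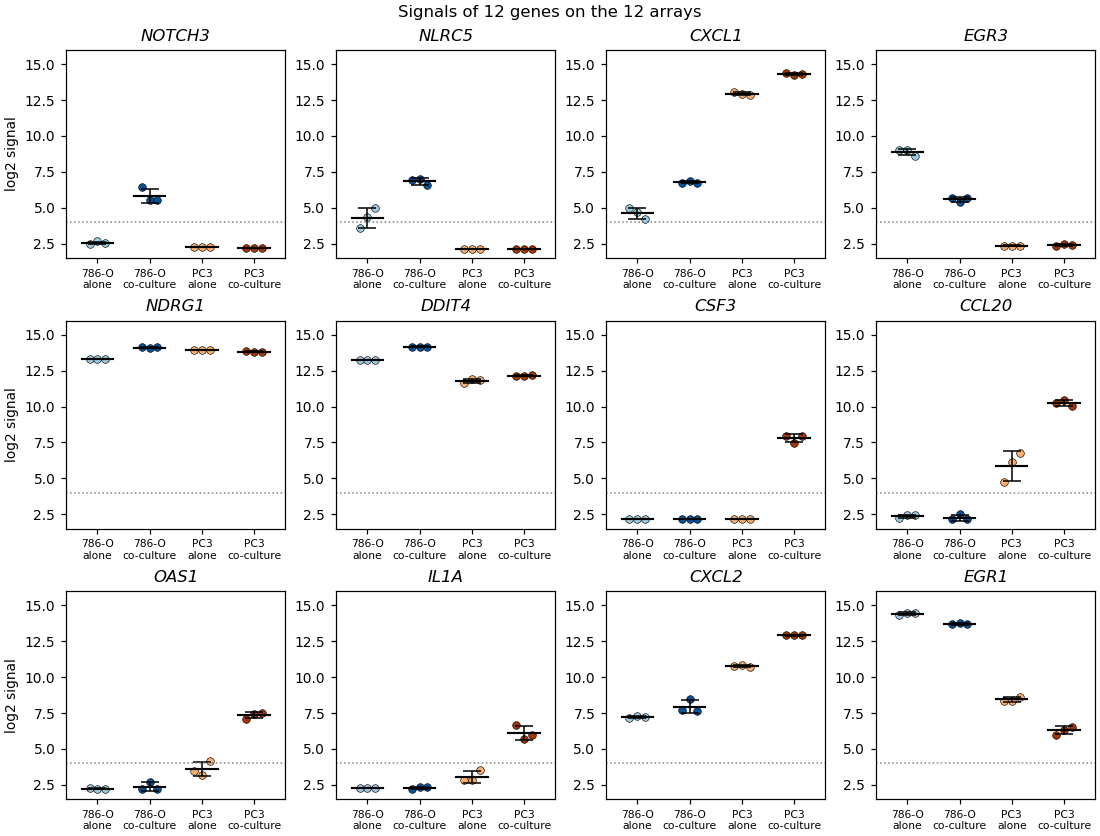
Log2 signal of 12 genes on each array, with the 4 groups side by side, horizontal bars at the mean, whiskers of 1 SD (n = 3) and a dotted line at the floor of log2 4. CSF3 lies at the floor in 3 groups and near 7.80 in co-cultured PC3, and EGR3 falls from 8.89 to 5.58 in 786-O.

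The second comparison asked the same of PC3 cells. CSF3, the granulocyte colony-stimulating factor, was under the floor alone and at least 13.9-fold higher in co-culture (log2 signal 7.80 ± 0.27 (SD, n = 3), adjusted p = 3.39e-09). CCL20, a chemokine for lymphocytes and dendritic cells, rose with a log2 fold change of 4.39 ± 0.38 (SE, adjusted p = 2.66e-05). OAS1, an antiviral enzyme that senses double-stranded RNA, had its mean alone under the floor and was at least 10.2-fold higher (adjusted p = 3.13e-06). TNFAIP6, a hyaluronan-binding protein induced by inflammation, was at least 3.45-fold higher (adjusted p = 4.54e-07). EGR1, an immediate early transcription factor, fell by 2.16 ± 0.13 on the log2 scale (adjusted p = 1.42e-06).

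The other large rises in PC3 were ARNT2, a bHLH-PAS transcription factor, at least 10.1-fold, TCIM at least 8.47-fold, CEACAM6, a cell adhesion protein, at least 6.15-fold, INSL4, a relaxin family peptide, at least 4.58-fold, ARL14 at least 17.6-fold, and HAO1, a peroxisomal oxidase, with a log2 fold change of 3.78. NEFM, a neurofilament protein, was at least 4.22-fold lower. CCDC85A was at least 5.08-fold lower and IL1RAPL1 at least 3.32-fold. MAP7D3, HHIP, an antagonist of hedgehog signalling, CFAP251, PLPPR5 and C9orf148 fell with log2 fold changes from -2.63 to -2.01, in that order. The fall of SNHG4, a noncoding RNA, at least 2.12-fold (adjusted p = 0.0407), lost its call in 9 of 12 omissions of an array, with 0.166 at most, without replicate 1 of the co-culture.

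NF-kappaB target genes rose together in PC3. Of 24 measured members 15 rose and 0 fell, or 17 and 0 adjusted over the list alone, and the median log2 change was 0.62 (camera adjusted p = 6.53e-21; adjusted p = 0.00153 with an estimated correlation). The neutrophil chemokines CXCL2 and CXCL3 rose with 2.15 ± 0.17 and 2.45 ± 0.21, and the cytokine IL1A was at least 4.27-fold higher. Interferon response genes followed, with 9 of 25 higher and 0 lower, or 15 and 0 adjusted over the list alone, and a median of 0.51 (adjusted p = 1.62e-13; adjusted p = 0.000898 with an estimated correlation). OASL, an antiviral protein, rose with 1.24 ± 0.10, IFI44L with 1.80 ± 0.16 and IFI44 with 0.83 ± 0.08. Both calls were kept without each of the 12 arrays in turn.

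YAP and TEAD targets fell in PC3, with 2 of 16 higher and 6 lower (2 and 7 adjusted over the list alone) and a median of -0.11, or -0.09 with signals under the floor set to it (adjusted p = 0.0024; adjusted p = 0.127 with an estimated correlation). CCN2, a matricellular growth factor, stood at -1.08 ± 0.11, FJX1 at -0.53 ± 0.05 and NT5E, an enzyme that makes adenosine, at -0.48 ± 0.06, while F3, tissue factor, rose with 0.53 ± 0.07. Genes of the G2 and M phases of the cell cycle fell, with 0 of 24 higher and 3 lower (0 and 6 adjusted over the list alone), among them MKI67, a proliferation marker, at -0.45 ± 0.08, CCNB1, a mitotic cyclin, at -0.18 ± 0.04 (0.14 without probe sets that may bind several transcripts, where it did not pass) and CENPE, a kinetochore motor, at -0.41 ± 0.11. Their median was -0.07 (camera adjusted p = 0.00151, and adjusted p = 0.523 with an estimated correlation). In limma's directional fry test, another test of lists, the call of the G2 and M phases was lost (adjusted p = 0.0693). In the camera test the calls of both lists were kept without each array. The median of YAP and TEAD targets was -0.06 without replicate 1 and -0.18 without replicate 3 grown alone. That of the G2 and M phases was -0.11 without replicate 2 of the co-culture and -0.11 without replicate 1 grown alone.

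A further 3 lists passed narrowly in PC3. Integrin and adhesion genes had 3 of 24 higher and 1 lower (8 and 3 adjusted over the list alone; median 0.11, or 0.08 with signals under the floor set to it, adjusted p = 0.0469; adjusted p = 0.523 with an estimated correlation), with ICAM1 at 0.82 ± 0.09, THBS1, an inhibitor of angiogenesis, at 0.78 ± 0.12 and ITGA5, a fibronectin receptor chain, at 0.38 ± 0.06. Of the unfolded protein response 0 of 18 members passed either way over all genes or adjusted over the list alone (median 0.09, adjusted p = 0.0279; adjusted p = 0.127 with an estimated correlation). Of the genes of the G1 and S phases 0 of 22 rose and 1 fell, over all genes and adjusted over the list alone, which was MCM4, a part of the replicative helicase, at -0.51 ± 0.09 (list median -0.05, adjusted p = 0.0469; adjusted p = 0.602 with an estimated correlation). These calls were lost in 7, 3 and 11 of the 12 omissions. The adjusted p was then up to 0.125 without replicate 2 grown alone, 0.0685 without replicate 2 of the co-culture and 0.0992 without replicate 3 grown alone. With the mean of probe sets each was lost (adjusted p = 0.125), and under quantile normalization too (0.0646, 0.0605 and 0.0547). The call of integrin genes was also lost without a filter (0.106), with arrays centred (0.0769) and with the ACTB ratio in the fit (0.0894). That of the G1 and S phases was also lost with arrays centred (0.0769) and in the directional fry test (0.25). With a block for the repeat number the calls of integrin genes and of the G1 and S phases were lost (0.0508 for each).

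Other PC3 genes changed without a call of their list. Of TGF-beta and SMAD targets 5 of 21 rose and 4 fell, over all genes and adjusted over the list alone (adjusted p = 0.734). PMEPA1, a brake on TGF-beta signalling, rose 2.63-fold (adjusted p = 4.28e-09). Of hypoxia targets 4 of 30 rose and 4 fell (6 and 7 adjusted over the list alone; adjusted p = 0.462), with BHLHE40, a transcriptional repressor, at 0.67 ± 0.08 and SLC2A1 at 0.54 ± 0.08. In all, 713 of 12502 genes were called in PC3, 399 higher and 314 lower, of which 138 and 56 changed at least 2-fold. The groups of 27.3% of all genes did not overlap, where chance gives 10%. The count was 434, 435, 452 and 475 without replicate 2 alone, replicate 1 in co-culture, replicate 3 alone and replicate 3 in co-culture. It was 1314 without replicate 2 of co-cultured 786-O, whose spread enters the shared variance. With only the arrays of PC3 in the fit 805 genes were called, against 175 in 786-O with only its own arrays. Which line had more called genes thus depended on the fit. The PC3 count was 419 with the filter at the 75th percentile and 4532 with array weights, which did not converge. In fits added after the data were seen it was 3525 with weights fitted gene by gene and 1385 with the ACTB ratio.

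The third comparison tested whether the lines differed in their response. NF-kappaB targets responded less in 786-O than in PC3: 11 of 24 had a lower and 0 a higher response (11 and 1 adjusted over the list alone), with a median log2 difference of -0.51, or -0.48 with signals under the floor set to it (adjusted p = 4.16e-08; adjusted p = 0.0341 with an estimated correlation). The cytokine IL11 differed by -1.14 ± 0.16, having fallen in 786-O and risen in PC3, while IL1A, CCL20 and CXCL6 were under the floor in both 786-O groups. Interferon response genes differed in the same direction, with 5 of 25 lower and 0 higher over all genes and adjusted over the list alone, and a median of -0.26 (adjusted p = 0.000785; adjusted p = 0.0341 with an estimated correlation). IFIT1, which binds viral RNA, differed by -1.21 ± 0.15 and IFI44L by -1.91 ± 0.23.

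Hypoxia targets responded more in 786-O: 8 of 30 had a higher and 0 a lower response (11 and 1 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.000808; adjusted p = 0.329 with an estimated correlation). NDRG1 differed by 0.93 ± 0.04 (adjusted p = 3.8e-07), ADM by 0.86 ± 0.12 and DDIT4 by 0.54 ± 0.08. ATF4 target genes followed with 6 of 27 higher and 0 lower (11 and 0 adjusted over the list alone), a median of 0.18 (0.12 with signals under the floor set to it; adjusted p = 0.00715; adjusted p = 0.329 with an estimated correlation), and SLC7A11 at 0.57 ± 0.10 and ASNS, asparagine synthetase, at 0.35 ± 0.07. The calls of these 4 lists were kept without each array in turn, but that of ATF4 targets was lost with the mean of each gene's probe sets (median 0.09, adjusted p = 0.133).

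Cell cycle genes of the G1 and S phases (2 of 22 higher and 0 lower, over all genes and adjusted over the list alone) and of the G2 and M phases (2 of 24 higher and 0 lower, or 3 and 0 adjusted over the list alone) also had a positive difference, with MKI67 at 0.72 ± 0.11 and CENPF, a kinetochore protein, at 0.65 ± 0.13. The adjusted p-values of the difference were 0.0323 and 0.0377, and with an estimated correlation adjusted p = 0.753 and 0.715. Both lists were called lower in PC3, and neither was called in 786-O (medians 0.10 and 0.02, camera adjusted p = 0.351 and 0.921). The difference therefore does not show a larger response of these lists in 786-O. Of the unfolded protein response 0 of 18 differed (1 higher and 4 lower adjusted over the list alone), with a median of -0.18 (adjusted p = 0.0377; adjusted p = 0.22 with an estimated correlation). These 3 calls were lost in 3, 6 and 4 of the 12 omissions. Both cell cycle calls reached 0.151 without replicate 2 of co-cultured 786-O, the array that stood apart, and the third reached 0.0597 without replicate 2 of co-cultured PC3. With the mean of probe sets the 3 calls were lost too (adjusted p = 0.303, 0.0857 and 0.143). Those of the cell cycle lists were also lost with arrays centred (0.053 and 0.0716) and with the ACTB ratio in the fit (0.135 and 0.168). In the directional fry test the cell cycle calls were lost too (0.111 and 0.0878). The third was also lost under quantile normalization (0.115) and without a filter (0.239).

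The response differed in 746 of 12502 genes, higher in 786-O in 425 and lower in 321. With each array centred on its median the split was 319 and 355, and with array weights, which did not converge, 557 and 705. It was 1932 and 1915 with weights fitted gene by gene, and 908 and 975 with the ACTB ratio in the fit. Both of these fits were added after the data were seen. The count was 468, 401 and 395 without replicates 1, 2 and 3 of 786-O alone. It was 1314 and 1138 without replicates 2 and 3 of co-cultured 786-O, 397 and 459 without replicates 1 and 3 of co-cultured PC3, and 410 and 399 without replicates 2 and 3 of PC3 alone. The median log2 difference over all genes was 0.02.

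**Figure D3:**
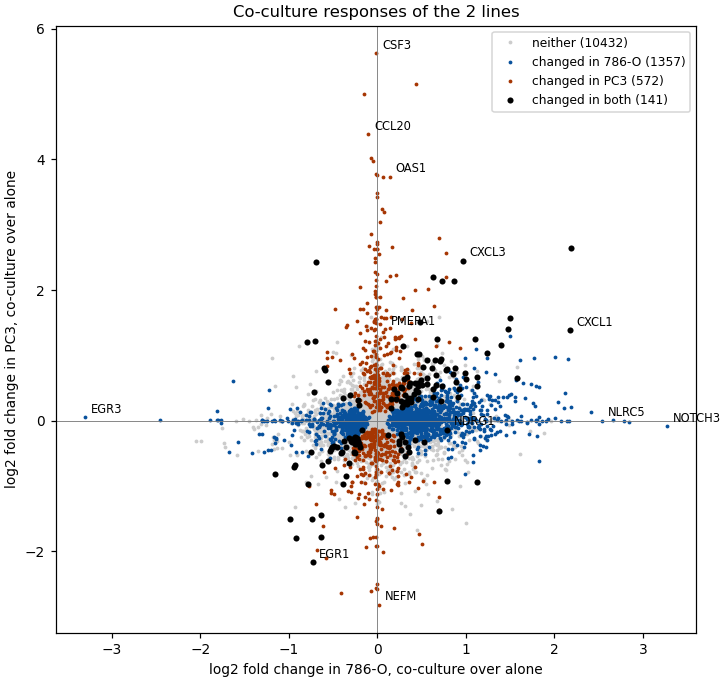
Log2 fold change of co-culture over alone in 786-O (horizontal) and PC3 (vertical) for 12502 genes, coloured by the line in which each was called. The vertical arm holds genes such as CSF3 and CCL20 that changed in PC3 and lay at the floor in 786-O, and the horizontal arm holds NOTCH3 and EGR3.

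A set of genes changed in both lines. Genes higher in both numbered 73, where independent lists would share 32.2 (Fisher's exact test, two-sided, p = 3.16e-11, adjusted over 4 overlaps 6.32e-11), and genes lower in both numbered 41 against 12.3 (p = 8.55e-12, adjusted 3.42e-11). The tests of all 4 overlaps treat genes as independent and as equally open to a call in both lines. Related genes such as CXCL1, CXCL2 and CXCL3 were among the 73, and genes at the floor in 1 line can hardly be called there. The p-values and expected numbers are therefore only a rough guide. The genes named in this paragraph were chosen after their values were seen. Higher in both were BCL3, a regulator of NF-kappaB, 2.83-fold in 786-O and 2.98-fold in PC3, CXCL8 with log2 fold changes of 0.56 and 0.66, ICAM1 with 0.52 and 0.82, PSMB9 with 0.72 and 0.94, SLC2A1 with 0.51 and 0.54, and AKR1C3, an aldo-keto reductase, with 1.00 and 0.64. Lower in both were EGR1 with -0.73 and -2.16, DUSP5, a phosphatase that ends ERK signalling, with -0.32 and -0.65, ID3 with -0.93 and -0.68, and RGS4, a regulator of G protein signalling, with -1.15 and -0.82. The larger fall of EGR1 in PC3 rests on the 1 probe set used. With the mean of its probe sets the difference of responses was -0.13 and did not pass (limma adjusted p = 0.688).

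Genes called in opposite directions were not more common than independent lists would give by Fisher's exact test: 16 were higher in 786-O and lower in PC3 against 25.4 (p = 0.0579, adjusted 0.0772), and 11 the other way against 15.6 (p = 0.292, adjusted 0.292). Among them, chosen after their values were seen, were MMP1, a collagenase, with 0.31 in 786-O and -0.54 in PC3, MKI67 with 0.27 and -0.45, THBS1 with -0.59 and 0.78, and TGFB2 with -0.72 and 0.44. Across the 12502 genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.104 and a Spearman correlation of 0.1003. The 114 genes shared in the same direction became 200 and 161 without replicates 2 and 3 of co-cultured 786-O. They became 67, 55 and 59 without replicates 1, 2 and 3 of 786-O alone, 70 without replicate 2 of PC3 alone and 71 without replicate 1 of co-cultured PC3. In fits added after the data were seen they became 730 with weights fitted gene by gene and 220 with the ACTB ratio.

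**Figure D4:**
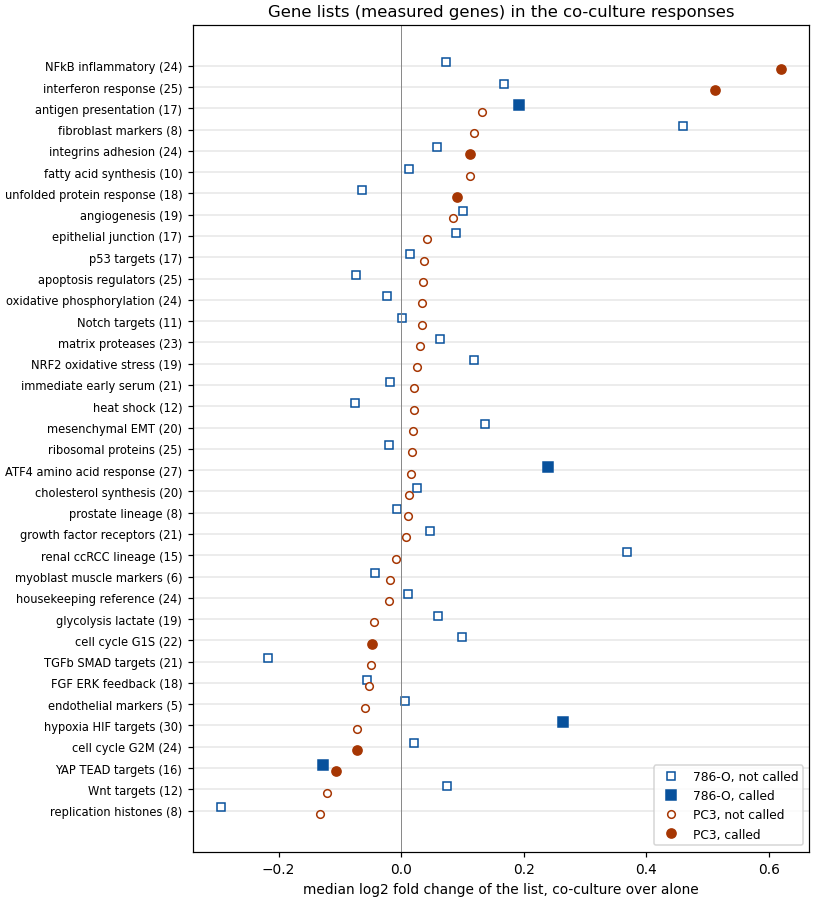
Median log2 fold change of co-culture over alone for the 36 gene lists tested, with the number of measured genes in brackets, in 786-O (squares) and PC3 (circles); filled symbols mark lists with a camera adjusted p under 0.05. NF-kappaB and interferon genes lie at 0.62 and 0.51 in PC3, and hypoxia and ATF4 targets at 0.26 and 0.24 in 786-O.

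The fourth comparison set the lines against each other without myoblasts, where they differed in most genes. UCHL1, a deubiquitinase, was at least 1592-fold higher in 786-O, CTNNA1, the alpha-catenin of adherens junctions, at least 837-fold, and SPP1, the matrix protein osteopontin, at least 657-fold. PC3 had at least 1556-fold more PI3, the elastase inhibitor elafin, at least 1088-fold more IL1B, the cytokine interleukin-1 beta, and at least 1359-fold more DKK1, an inhibitor of Wnt signalling. For these 6 genes the adjusted p was at most 6.34e-12. RFLNB, PTGFRN, SLFN11, BCAT1, CADM1 and IGFBP7 were at least 436.5-fold higher in 786-O. SRGN, IGFBP4, TFF1, PRSS3, TSPYL5 and CDH11 were at least 669-fold higher in PC3, and KRT81, a keratin, had a log2 difference of -11.20 ± 0.33.

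Renal lineage genes were higher in 786-O, with 12 of 15 higher and 2 lower over all genes and adjusted over the list alone. PAX8, a kidney transcription factor, was at least 47.6-fold, CP, ceruloplasmin, at least 163-fold and CDH6, kidney cadherin, at least 30.5-fold higher. CA9, carbonic anhydrase 9, was instead at least 63.4-fold higher in PC3. The list's median was 2.83, or 2.24 with signals under the floor set to it (adjusted p = 0.00954; adjusted p = 0.129 with an estimated correlation). NF-kappaB genes were lower in 786-O (5 of 24 higher and 16 lower; median -1.62, adjusted p = 0.0231; adjusted p = 0.328 with an estimated correlation), with CXCL1 at -8.34 ± 0.16 and CXCL8 at -4.15 ± 0.11. So were FGF and ERK feedback genes (2 of 18 higher and 15 lower; median -0.99, adjusted p = 0.00166; adjusted p = 0.129 with an estimated correlation), with the ERK phosphatases DUSP4 at -5.24 ± 0.10 and DUSP6 at -2.80 ± 0.12, and histone genes (0 of 8 higher and 8 lower; median -3.69, adjusted p = 0.00166; adjusted p = 0.282 with an estimated correlation), with H2BC12 at -1.54 ± 0.07. The counts of these last 3 lists were the same adjusted over the list alone. In all, 9372 of 12502 genes were called, 4631 higher in 786-O and 4741 lower. The groups of 83.4% did not overlap, where chance gives 10%.

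The fifth comparison set the lines against each other in co-culture, which the series title names. UCHL1 was at least 1558-fold, NEFM at least 1757-fold and CTNNA1 at least 960-fold higher in 786-O, and IL1B at least 1760-fold, PI3 at least 1619-fold and KRT81 at least 2811-fold higher in PC3, each with an adjusted p of at most 1e-11. RFLNB, SPP1, PTGFRN, CA2, CCND2 and BCAT1 were at least 517-fold higher in 786-O, and SRGN, IGFBP4, TFF1, PRSS3, DKK1, CDH11 and TSPYL5 at least 669-fold higher in PC3. Of 12502 genes 9522 were called, 4818 higher in 786-O and 4704 lower. The groups of 76.8% did not overlap, where chance gives 10%. Of the genes called alone and in co-culture 8267 had the same direction and 45 the opposite one.

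Interferon response genes were lower in 786-O (4 of 25 higher and 14 lower; median -0.96, adjusted p = 0.0451; adjusted p = 0.176 with an estimated correlation), with OASL at -3.14 ± 0.10 and RIGI, a sensor of viral RNA, at -2.96 ± 0.12. Epithelial junction genes (3 of 17 higher and 12 lower; median -1.73, or -1.21 with signals under the floor set to it) and fibroblast markers (1 of 8 higher and 6 lower; median -2.76) each had an adjusted p = 0.0451, and with an estimated correlation adjusted p = 0.176 and 0.605. EPCAM, an epithelial adhesion molecule, was at least 316-fold and KRT7, a keratin of simple epithelia, at least 638-fold higher in PC3, while DSP, desmoplakin, was at least 295-fold higher in 786-O, and FBN1, fibrillin, had a log2 difference of -5.19 ± 0.16. These 3 lists did not pass alone, where interferon genes had 5 higher and 13 lower (median -1.06, adjusted p = 0.318), epithelial junction genes 3 and 12 (-1.37, adjusted p = 0.0726) and fibroblast markers 2 and 6 (-2.93, adjusted p = 0.0726), and a change between the conditions is not shown by that. The 3 calls in co-culture were lost without replicate 1 of PC3 alone (adjusted p = 0.0551 for each) and replicate 3 of PC3 alone (0.0504, 0.0504 and 0.0526, in the order given). That of interferon genes was also lost with the mean of probe sets (0.0801). The call of epithelial genes was lost under quantile normalization (0.0508) and without replicate 1 of co-cultured 786-O (0.051), and the call of fibroblast markers was lost without replicate 3 of 786-O alone (0.0538). The lists called alone were called again. NF-kappaB genes had 4 of 24 higher and 17 lower (median -2.28, or -2.08 with signals under the floor set to it; adjusted p = 0.00315; adjusted p = 0.176 with an estimated correlation). FGF and ERK feedback genes had 2 of 18 higher and 14 lower (median -1.17, adjusted p = 0.00315; adjusted p = 0.102 with an estimated correlation), and histone genes 0 of 8 higher and 8 lower (median -4.10, adjusted p = 0.00106; adjusted p = 0.176 with an estimated correlation). Renal lineage genes had 12 of 15 higher and 2 lower, or 13 and 2 adjusted over the list alone (median 3.18, or 2.69 with signals under the floor set to it; adjusted p = 0.00377; adjusted p = 0.102 with an estimated correlation). For the other 6 lists of this paragraph both counts were the same adjusted over the list alone.

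Markers of the partner cells were looked for on the human probe sets, which see mouse RNA only where it binds across species. The muscle regulators MYOD1, MYF5 and MYOG and the muscle filament DES reached signals of 4.5, 5.0, 4.4 and 7.3 at most on any array, all under the floor. Of the 34 myoblast and muscle markers listed 32 had a probe set and 6 were bright enough to be tested. MEF2C, a muscle and immune transcription factor that PC3 itself expressed at a mean signal of 7087 ± 303 (SD, n = 3) alone, was lower in co-cultured PC3 at 4940 ± 135 (adjusted p = 0.00149). Fibroblast markers did not pass in either response, though COL1A1, a collagen of connective tissue, rose in 786-O with 0.78 ± 0.20 (adjusted p = 0.0321; 0.50 without replicate 2 of the co-culture) and in PC3 with 0.77 ± 0.20 (adjusted p = 0.0498).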

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

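The test for mouse RNA and the fits with the ACTB 3' to 5' ratio as a covariate were chosen only after the data were seen. The results here were singled out because the response to co-culture differed between the lines in the test of the difference itself, or because 1 array lay apart from its group. The response differed in 746 genes. With the arrays regrouped at random within each line, 1 of 100 groupings, the real one, reached that count, and the highest other gave 571, in a grouping that kept the real 786-O groups and regrouped PC3. Chance can be excluded for the count only in the sense that arrays put together at random do not give it: each other grouping takes away the response of at least 1 line, so none stands for lines with equal responses. For the 7 gene lists called in the difference, 5 of 100 groupings gave as many, with 8 at most. Each other grouping that gave as many kept the real groups of 1 line, and those that kept neither gave 6 at most. That share thus does not measure chance alone, and chance is not excluded for the number of lists. For the 114 genes shared in direction 1 of 100 groupings, the real one, reached the count and the highest other gave 0. Regrouping a line takes its response away, and 5 genes at most were then called in the line with fewer, so the groupings say nothing about sharing by chance.

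Each comparison between a pair of groups allows 10 splits of its 6 arrays, too few for a share under 0.05. The real split called 1498 genes in 786-O (highest other 5), 713 in PC3 (1), 9372 between the lines alone (0) and 9522 between them in co-culture (0), and 1 split reached the count in each. For gene lists the real split called 4 in 786-O (highest other 3), 7 in PC3 (4), 4 between the lines alone (4) and 7 between them in co-culture (3), and 1, 1, 2 and 1 splits reached those numbers.

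The larger response of NF-kappaB and interferon genes in PC3 than in 786-O was the first pattern, with median log2 differences of -0.51 and -0.26 and of -0.36 over the 49 members. Uneven RNA quality that follows the ACTB ratio would have taken the difference away with that ratio in the fit, yet the median was then -0.38. Quality effects that the ratio does not follow are not excluded by this. Members at the floor in 786-O cannot be the whole cause, since the median over the 37 members above it in all groups was -0.25, from -0.27 to -0.19 without each array in turn. Mouse RNA bound by the human probe sets stays open: the median log2 change of 32 muscle markers in PC3 was 0.0045, but 27 of them lay under the floor on every array and need not bind mouse transcripts, so the bound set for that median decided nothing. A line-specific response to the myoblasts is a candidate explanation, but medium, serum, density and the hours before sampling in the wells without myoblasts were not separated from it.

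The rise of hypoxia and ATF4 targets in 786-O was the next, with a median log2 change of 0.24 over 56 members and median differences between the responses of 0.33 for hypoxia and 0.18 for ATF4 targets. If replicate 2 of the co-culture alone carried it, the rise would have gone without that array, yet the median was then 0.196. If the co-culture arrays lay higher as a whole, centring each array on its median would have removed it, yet the median was then 0.226. A response to the partner cells may account for it, and so may a medium used up faster with more cells in the well, which these samples cannot tell from it.

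The last was replicate 2 of co-cultured 786-O, whose ACTB ratio was 7.22. RNA of PC3 in this sample would have raised genes that PC3 has and 786-O lacks, yet the median log2 deviation of such genes was 0.0108. RNA of cells grown alone would have shrunk its response, yet its median ratio to that of replicates 1 and 3 was 1.07 over 1546 genes. Uneven labelling from the 3' end may contribute and stays open: the array's deviation had a correlation across genes of 0.161 with the slope on the ACTB ratio in PC3 (0.267 among bright genes), against -0.239 to 0.047 on the other 786-O arrays. No biological explanation was tested for a single array.

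The other lists that differed were the genes of the G1 and S phases (median log2 difference 0.16, or 0.09 without replicate 2 of co-cultured 786-O), of the G2 and M phases (0.09) and of the unfolded protein response (-0.18). Among called genes, the highest fitted differences were those of NOTCH3 (log2 difference 3.36), AMBN (2.86), NEFM (2.84), KRT79 (2.79), CFAP251 (2.57), LINC00937 (2.56), CCDC85A (2.54), NLRC5 (2.54), HHIP (2.53) and PLPPR5 (2.50). The call of LINC00937 (adjusted p = 0.0435) was lost in 10 of 12 omissions of an array, with 0.0991 at most, without replicate 1 of 786-O alone. The lowest fitted differences were those of CSF3 (-5.63), ARL14 (-5.145), ARNT2 (-4.73), CCL20 (-4.49), TCIM (-4.08), CEACAM6 (-4.02), HAO1 (-3.79), INSL4 (-3.76), TNFAIP6 (-3.66) and OAS1 (-3.59). These fitted differences are no bounds and their order need not be that of the true sizes, since the signals of most of these genes lay under the floor in 1 or more groups; TNFAIP6 was bright in 786-O in both conditions (log2 9.96 with myoblasts and 9.90 alone), as was NEFM (14.78 and 14.76).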

How the results depend on the processing

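The array weights fitted gene by gene, the ACTB 3' to 5' ratio as a covariate, the filter on group means of at least 5 and the adjusted p of the authors' test were chosen only after the data were seen. Of 341 named gene results that passed, 326 kept their call under quantile normalization, 317 with arrays centred, 283 without a filter, 332 with 32 added to the signals, 304 without an intensity trend, 335 with a robust one, 302 with the mean of probe sets, 337 of 337 with the filter on group means, and 267 to 330 without each array. It was kept by 273 with array weights, 265 with a block for the repeat number, 237 at a threshold of 0.01, 184 at a change of at least 2-fold, and 175 of 260 with only the arrays compared. These numbers include 35 results between the lines alone and 47 in co-culture, which all kept their call and raise the shares. In the 786-O response 38 kept it and 60 lost it with array weights. The numbers there were 67 and 31 with the block, 49 and 49 at 0.01, and 57 and 41 without replicate 2 grown alone. Of 29 list results that passed, 24 kept their call under quantile normalization, 25 with arrays centred, 26 without a filter, 21 with the mean of probe sets, 25 in the directional fry test and 4 with an estimated correlation. Using the series matrix in place of the authors' table changed nothing, since the values are equal. The numbers of called genes that moved were as follows, in the order 786-O response, PC3 response, difference, lines alone, lines in co-culture and genes shared in direction, as far as they moved. Fewer genes tested at the 75th percentile left 419 in PC3, 478, 6157 and 6223; without a filter 963 were called in 786-O. Only the arrays compared gave 175 in 786-O, but 805 in PC3 and 9935 between the lines alone. Testing every probe set gave 16013 and 16412 for the lines alone and in co-culture. A threshold of 0.01 left 397, 349, 230 and 33 shared, and a change of at least 2-fold left 207, 194, 251, 4022, 4128 and 7. Array weights did not converge and gave nearly no weight to replicate 1 of co-cultured 786-O, with 309, 4532 and 1262; fitted gene by gene they gave 4087, 3525, 3847 and 730 shared. The ACTB covariate gave 1091 higher and 927 lower in 786-O, 1385 in PC3, 1883 and 220 shared. The authors' test after adjustment gave 11 in 786-O and 325 in PC3. A block for the repeat number gave 707, 411, 318 and 55 shared. Deviations of arrays with the same number correlated from -0.0578 to 0.0122 in 786-O and from -0.132 to 0.113 in PC3. Those of arrays with different numbers correlated from -0.0106 to 0.0657 and from -0.279 to 0.212. No pairing by number was seen, but 3 arrays per group are too few to settle whether the numbers pair the samples. Without each array the ranges were 536 to 2522, 434 to 1314, 395 to 1314, 8865 to 10006, 8986 to 9750 and 55 to 200. Where neither the number of genes or probe sets tested nor a stricter threshold sets the number, the cause was not tested. Results that reversed were, with the mean of probe sets, HK2 in 786-O (0.13) and, in the difference, MCM4 (-0.11), PHLDA1 (-0.0055) and EGR1 (-0.13); without probe sets that may bind several transcripts, FBN1 in 786-O (-0.0125), CCNB1 (0.14) and NDUFS1 (-0.16) in PC3, and RPL37 in the difference (0.63). The directional fry test called the opposite direction from camera for lists that camera did not call. These were matrix proteases (median 0.0154), mesenchymal genes (0.28) and muscle markers (-0.41) between the lines alone, and ATF4 targets (0.0267), mesenchymal genes (0.25) and muscle markers (-0.59) in co-culture; the cause was not tested. Changes of dim genes are seen only as far as signals rise over the floor. Over all simulated genes changed by 0.5 on the log2 scale, with equal spread in all groups, the fit called 50% in 786-O, 40.9% in PC3 and 27% in the difference.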

Other observations

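The adjustment of the authors' p-values was chosen only after the data were seen. Over all 12502 genes 1498 were called in 786-O and 713 in PC3, and the count of interferon genes below is close to that share. The members named had small p-values within their lists. In 786-O, single genes of lists for the extracellular matrix and for vessels changed without a call of the list. Matrix proteases and their inhibitors had 7 of 23 higher and 0 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.351), with PLAU, the urokinase, at a log2 fold change of 0.95 ± 0.14 (SE, n = 3 per group) and HPSE, heparanase, at 0.78 ± 0.17. Integrin and adhesion genes had 4 of 24 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.351), with LAMA3 and LAMB3, chains of laminin-332, at 1.28 ± 0.14 and 0.64 ± 0.12. Angiogenesis genes had 5 of 19 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.276), with EFNA1, an ephrin, at 1.28 ± 0.21 and EDN1, the vasoconstrictor endothelin-1, at 1.26 ± 0.21. Renal lineage genes had 4 of 15 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.0532), with NNMT, a nicotinamide methyltransferase, at 0.48 ± 0.05 and PAX8 at 0.79 ± 0.18. Interferon response genes had 3 of 25 higher and 0 lower over all genes and adjusted over the list alone (adjusted p = 0.0953), with IFIH1, a sensor of viral RNA, at 1.23 ± 0.29.

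In PC3, Notch pathway genes had 2 of 11 higher and 0 lower over all genes and adjusted over the list alone (adjusted p = 0.258): HES1, a Notch target, at 0.57 ± 0.07 and JAG1, a Notch ligand, at 0.34 ± 0.05. Epithelial junction genes had 2 of 17 higher and 1 lower (3 and 3 adjusted over the list alone; adjusted p = 0.405), with CLDN1, a tight junction protein, at 1.01 ± 0.08. Mesenchymal genes had 3 of 20 higher and 1 lower over all genes and adjusted over the list alone (adjusted p = 0.694), with ZEB2, a repressor of epithelial genes, at 1.72 ± 0.31 and VIM, vimentin, at -0.31 ± 0.06. Matrix proteases and their inhibitors had 3 of 23 higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.944), with the collagenase MMP13 at 1.02 ± 0.24 and the stromelysin MMP10 at least 1.51-fold higher, against the collagenase MMP1 at -0.54 ± 0.06.

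Called genes that were under the floor on all 3 arrays of a line alone and had a mean log2 signal of at least 5 in co-culture numbered 12 in 786-O and 14 in PC3, with 0 in both. Of called genes with several probe sets bright enough to test, 3 of 719 in 786-O and 2 of 353 in PC3 had another probe set called in the opposite direction. The authors' deposited p-values were under 0.05 for 19746 of 54675 probe sets in 786-O and 4689 in PC3. Among the 12502 genes tested here the numbers were 2370 and 2304, and 11 and 325 after adjustment. Probe sets at the floor were among the former, such as that of MYOD1, with a mean signal of 4.39 with myoblasts and 4.43 alone in 786-O.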
